A study of Streptomyces bingchenggensis with 16 samples.

How the data were processed

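RNA from mycelium of Streptomyces bingchenggensis, a soil actinomycete, was measured on single-colour Cy3 arrays at 16 times of a culture in Erlenmeyer flasks, in a producing medium based on sucrose and soybean. Each time of sampling had 1 array, so no time point had a replicate. Per the labels' protocols, RNA was isolated from pellets of small culture samples, column-purified, reverse transcribed, fragmented with DNase I and labelled. Each array is labelled as the only replicate of its time. The labels do not say whether successive samples came from 1 flask or from separate flasks, and they give no slide or hybridization batch.

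The deposited table holds log2 fold values for 10238 probes in 15 columns, and per the file headers the authors took the first sample, of 12 h, as the template of each fold. The 12 h array has no column of its own and is 0 for every probe by construction. Agilent Feature Extraction and limma are named in the submitters' processing notes, with no version. Background correction, normalization between arrays, filters and genome build are not given in the sources used here. The table names probes by the custom IDs of the array design and does not pair them with genes. Counts below are therefore counts of probes, and how many probes stand for 1 gene is unknown. Columns carry sample codes that were matched to hours through the series design text, and no column was left unmatched.

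Differences between any 2 columns, or between a column and 0, are differences between 2 arrays on the log2 scale and do not depend on the template, on the assumption that the deposited fold is a plain difference of normalized log2 signals. All 16 arrays were therefore used, with 12 h entered as 0. An error in a probe of the 12 h array enters all 15 deposited columns with the same sign. Signal levels cannot be recovered from folds, so neither dim nor saturated probes could be set apart, and the precision is limited by the number of arrays.

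The design was set before the data were examined, for log2 values per array; with folds in their place the same tests were kept. The arrays were placed in 4 windows of 4 consecutive samplings, 12 to 30 h, 33 to 45 h, 51 to 69 h and 72 to 144 h. A linear model with the 4 windows (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 12 residual degrees of freedom) gave the contrast of the last with the first window and the 3 contrasts of adjacent windows. A natural cubic spline with 3 degrees of freedom in log2 hours, tested with limma's moderated F, asked which probes changed along the course. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over the 10238 probes. Arrays of a window are different times and not replicates, so the SDs and standard errors include change within a window. Neighbouring times may also be correlated, which the models do not allow for. The p-values of the spline therefore measure departure from a flat course among these 16 arrays, and those of the contrasts a difference between window means. Neither measures error between cultures.

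Distances between arrays were taken as the median absolute log2 difference over all probes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9. By the rule fixed before the data were examined for a table without gene products, only the 2 probes that rose most and the 2 that fell most between the first and last windows are named. The planned tests of gene lists and of biosynthetic regions need gene products or locus tags and were not run.

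The models were tested on simulated data with independent normal errors and the residual SDs of the real probes. For the contrast of the last with the first window, 35 of 100 probes changed by 1 log2 unit and 82 of 100 changed by 2 log2 units were recovered among 10238 probes, with 2 false calls. For the spline, 4 of 100 probes with a rise or fall of 1 log2 unit over the course and 50 of 100 with 2 log2 units were recovered, with 3 false calls. Far fewer probes were changed here than were called in the data, which makes the adjusted threshold stricter. The recovered shares therefore do not give the sensitivity of the calls below. Alternatives were centring of each array on its median, other spline settings and time scales, linear trends, other windows, the 8 arrays of the outer windows alone, a 2-fold minimum, and leaving out each array in turn. Robust eBayes, the omission of pairs of arrays, the division of the first window and the centring of arrays before distances were taken were added after the data were seen.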

Results

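Streptomyces bingchenggensis is a filamentous soil bacterium known as a producer of milbemycins, macrocyclic lactones used against mites and insects. Its transcriptome was followed through a fermentation, and the series title gives the capacity for secondary metabolism as the subject. Mycelium was sampled 16 times between 12 and 144 h, at intervals of 3 to 9 h up to 72 h and of 24 h from then on, with 1 array per time. For tests of stages, the samplings were placed in 4 windows of 4 arrays, 12 to 30 h, 33 to 45 h, 51 to 69 h and 72 to 144 h. The data comprised 10238 probes, each given as a log2 fold against the 12 h array. The design implies a comparison of every later time with 12 h and of successive stages of the course with each other. The probes are not paired with genes in the data used here, so the changes are described for probes and for the times at which they occurred.

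The 18 h array resembled the 12 h array, and at 24 h many more probes differed from 12 h. At 18 h, 536 probes lay at least 2-fold above and 344 at least 2-fold below 12 h, 8.60% of all probes. At 24 h the numbers were 1426 above and 1358 below, 27.2% of all probes. From 30 to 72 h the share stayed between 29.7% (30 h) and 37.2% (69 h), with more probes below than above 12 h in every array of this range. The share was highest at 120 h, with 2116 probes above and 2083 below, 41.0%. At 96 h 1815 probes lay above and 1797 below, and at 144 h 1660 lay above and 1854 below. These counts compare single arrays and have no replicate check. The median log2 fold of the 15 arrays lay between -0.07 (96 h) and 0.02 (120 h); how the arrays were normalized before the fold, which can fix this median, is not given in the sources used here.

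**Figure D1:**
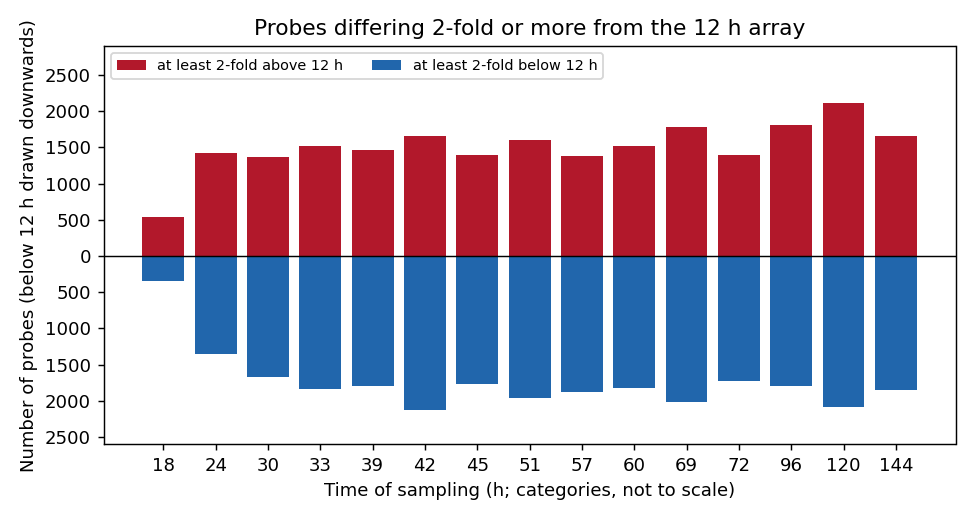
Number of probes (vertical axis) at least 2-fold above (red, upwards) or below (blue, downwards) the 12 h array at each later time of sampling (horizontal axis, h, as categories); each pair of bars is 1 array. The number above 12 h went from 536 at 18 h to 1426 at 24 h and stood at 2116 at 120 h.

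Distances between arrays set the first samplings apart from the rest, and the last ones less evenly. The 12 h and 18 h arrays were close to each other, with a median absolute log2 difference of 0.29, and both were far from the 24 to 72 h arrays, with 22 distances between 0.56 and 0.75. The 10 arrays from 30 to 72 h lay within 0.21 to 0.42 of each other. The 96 h and 144 h arrays lay 0.23 apart, whereas 96 h lay 0.55 to 0.78 and 144 h 0.47 to 0.68 from the 24 to 72 h arrays. The 120 h array lay 0.43 to 0.53 from the 24 to 72 h arrays, which lay up to 0.47 from each other. The 120 h array did not lie between its neighbours in time. It was 0.63 from 96 h, 0.54 from 144 h and 0.43 from its nearest array, that of 39 h. Among adjacent samplings the step from 18 to 24 h was 0.56, against 0.24 to 0.33 for the other 5 steps of 6 h. At that step 2391 probes, 23.4%, moved by 2-fold or more. The 3 steps of 24 h at the end of the course measured 0.55, 0.63 and 0.54. The first principal component of the probe-centred values held 37.5% of the variance and separated 12 h and 18 h from the rest, and the second held 22.4% and separated 96 h and 144 h.

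**Figure D2:**
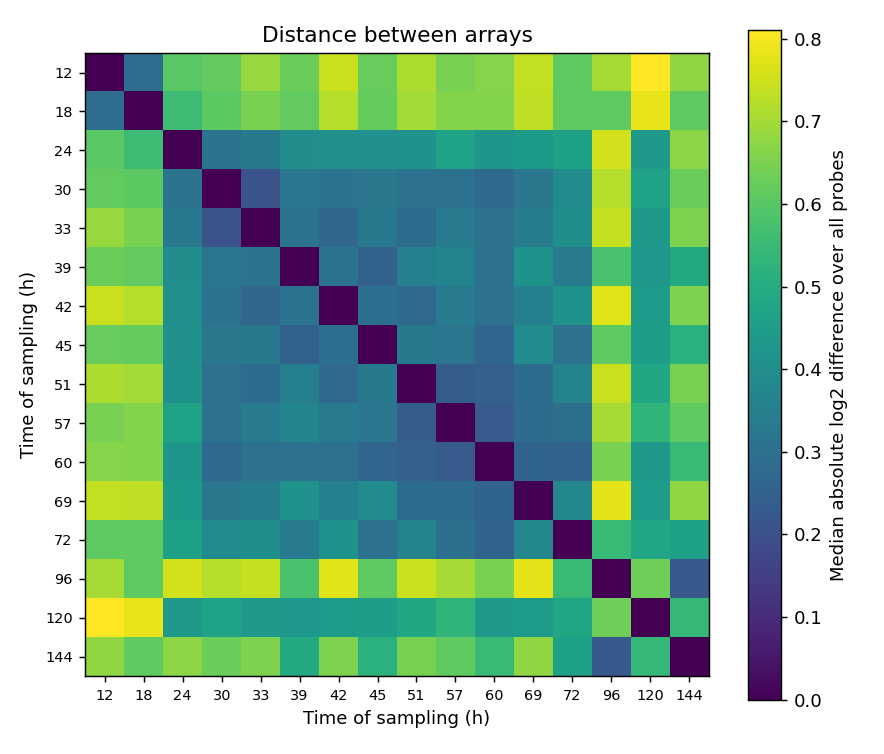
Median absolute log2 difference over all probes (colour) between each pair of the 16 arrays, with the time of sampling in h on both axes. The 12 h and 18 h arrays form a close pair at 0.29, the 30 to 72 h arrays a block at 0.21 to 0.42, and the 96 h and 144 h arrays a pair at 0.23 from which the 120 h array stands apart.

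Along the whole course, 4651 of the 10238 probes, 45.4%, changed by the spline test (limma's moderated F, adjusted p under 0.05). Among these, the window with the highest mean was the first for 1902 probes, the second for 462, the third for 771 and the last for 1516. The lowest mean fell in the first window for 1423, the second for 882, the third for 1024 and the last for 1322. Extremes in the outer windows were thus more frequent than extremes in the middle windows, for both highs and lows. This describes the called probes only. They were chosen by a smooth course over the same arrays, which can favour extremes at its ends. Without the 12 h and 18 h arrays 2179 probes changed, and the F-test over the 4 windows in place of the spline called 2783.

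Between the early culture of 12 to 30 h and the late culture of 72 to 144 h, 1211 probes rose and 1149 fell (limma, adjusted p under 0.05), together 23.1% of the probes. A change of at least 2-fold was reached by 765 of those that rose and 766 of those that fell. The median change was 1.16 log2 units among the probes that rose and -1.20 among those that fell, with a median standard error of 0.29 over all probes. Among all 10238 probes, called or not, the 4 late arrays all lay above the 4 early arrays for 1047 (10.2%) and all below them for 814 (7.95%), where exchangeable arrays would give 1.43% in each direction. Of these, 900 were among the probes called as rising and 729 among those called as falling. Of the 2360 called probes, 2137 also passed the spline test. Without the 96 h and 144 h arrays 447 probes rose and 481 fell, and without the 12 h and 18 h arrays 787 rose and 688 fell. In a fit of the 8 arrays of these windows alone 557 rose and 455 fell.

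The time by which 50% of the change was reached was taken from the window means. The probes were chosen by the difference of the first and last windows, which by itself tends to set those windows apart from the middle ones, so the timing is a description of the called probes. The first window also holds the step from 18 to 24 h, at which 23.4% of all probes moved by 2-fold or more. From 30 to 33 h 4.18% did. A change counted here at 33 to 45 h may thus have been reached by 24 h or 30 h. Of the 1211 probes that rose, 541 (44.7%) had reached 50% of their final change in the 33 to 45 h window, 179 reached it first at 51 to 69 h, and 491 (40.5%) only in the last window. Of the 1149 probes that fell, 682 (59.4%) had reached 50% of their change by 33 to 45 h, 171 at 51 to 69 h, and 296 (25.8%) only in the last window. The difference between the groups was not tested, since probes are not independent replicates. The median window mean of the rising probes was 0.30, 0.85, 0.85 and 1.43 log2 units above 12 h in the 4 windows in order. That of the falling probes was -0.30 in the first window, -0.95 in the second and -1.45 in the last.

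**Figure D3:**
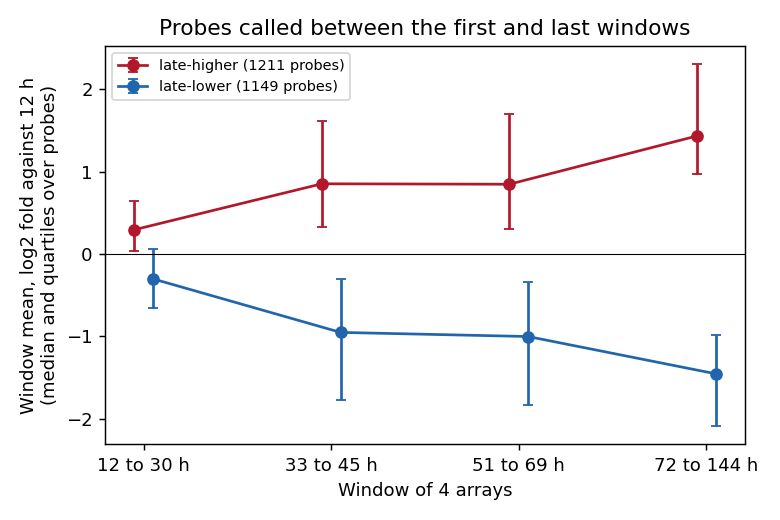
Window means as log2 fold against 12 h (vertical axis) in the 4 windows of 4 arrays (horizontal axis) for the 1211 probes that rose (red) and the 1149 that fell (blue) between the first and last windows; points are medians and bars the quartiles over probes. The medians of the rising probes are 0.30, 0.85, 0.85 and 1.43 in the 4 windows in order; the choice of probes by the first and last windows contributes to the distance of these from the middle windows.

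The 2 probes with the largest rise were CUST_3679_PI426192325 and CUST_3678_PI426192325, which carry consecutive numbers in the array design. CUST_3679_PI426192325 stood at -0.37 ± 0.62 (SD, n = 4 times) in the first window, 1.18 ± 1.00 in the second, 4.56 ± 1.21 in the third and 8.05 ± 1.15 in the last, in log2 units against 12 h. Its rise from the first to the last window was 8.42 log2 units with a standard error of 0.64, or 342-fold (limma, adjusted p = 1.16e-06). CUST_3678_PI426192325 rose by 8.30 log2 units with a standard error of 0.61, or 316-fold, with the same adjusted p from limma. It went from 0.29 ± 0.64 through 1.52 ± 0.84 and 4.90 ± 0.88 to 8.60 ± 1.37. Neither passed the test between the first and second windows (limma, adjusted p = 0.13 and 0.21). From the second to the third window CUST_3678_PI426192325 rose by 3.39 log2 units (adjusted p = 0.043), and CUST_3679_PI426192325, at 3.38, missed the threshold (adjusted p = 0.052). Both rose again from the third to the last window (adjusted p = 0.018 for each). These calls between adjacent windows, more than the sizes of the changes, depended on single arrays. The call of CUST_3678_PI426192325 from the second to the third window was lost without 24, 33, 39, 42, 45, 57, 60, 69, 96 or 120 h (limma, adjusted p up to 0.23), where its change was 2.99 to 3.61 log2 units, and CUST_3679_PI426192325 passed there without 12, 51 or 72 h. The calls of both from the third to the last window were lost without 51, 57, 96 or 144 h (adjusted p up to 0.081), with changes of 3.25 to 3.68 for CUST_3678_PI426192325 and 2.96 to 3.42 for CUST_3679_PI426192325. Without 96 h and 144 h together the changes were 2.80 and 2.89 (adjusted p = 0.37 and 0.40).

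The 2 probes with the largest fall, CUST_7837_PI426192325 and CUST_7838_PI426192325, also carry consecutive numbers. CUST_7837_PI426192325 fell by 5.18 log2 units between the first and last windows, with a standard error of 0.47, or 36.3-fold (limma, adjusted p = 5.86e-06). Its window means were -0.43 ± 0.63, -2.07 ± 0.56, -4.81 ± 0.91 and -5.61 ± 0.80 (SD, n = 4 times). CUST_7838_PI426192325 fell by 4.93 log2 units, with a standard error of 0.34, or 30.5-fold (adjusted p = 1.16e-06), through -0.53 ± 0.44, -2.10 ± 0.31, -4.50 ± 0.51 and -5.46 ± 0.70. Both fell between the first and second windows (adjusted p = 0.037 and 0.0098) and between the second and the third (adjusted p = 0.040 and 0.014). From the third to the last window neither passed the test, with changes of -0.80 and -0.96 log2 units (adjusted p = 0.26 and 0.077), although CUST_7838_PI426192325 passed there without 72 h (0.040). The calls of CUST_7837_PI426192325 were lost without 12, 18, 39, 42 or 45 h between the first and second windows (limma, adjusted p up to 0.14), with changes of -1.71 to -1.44. Between the second and the third they were lost without 24, 33, 39, 42, 45, 57, 60, 69, 96 or 120 h (up to 0.21), with changes of -2.94 to -2.37, and without 96 h and 144 h together (0.055). Those of CUST_7838_PI426192325 held between the first and second windows with any single array left out, and were lost between the second and the third without 39, 60 or 69 h (up to 0.092), with changes of -2.36 to -2.19. Without 12 h and 18 h together neither passed between the first and second windows (0.51 and 0.10). All 4 probes kept the direction and the call of the contrast of the last with the first window under every alternative that was run, including each array left out.

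**Figure D4:**
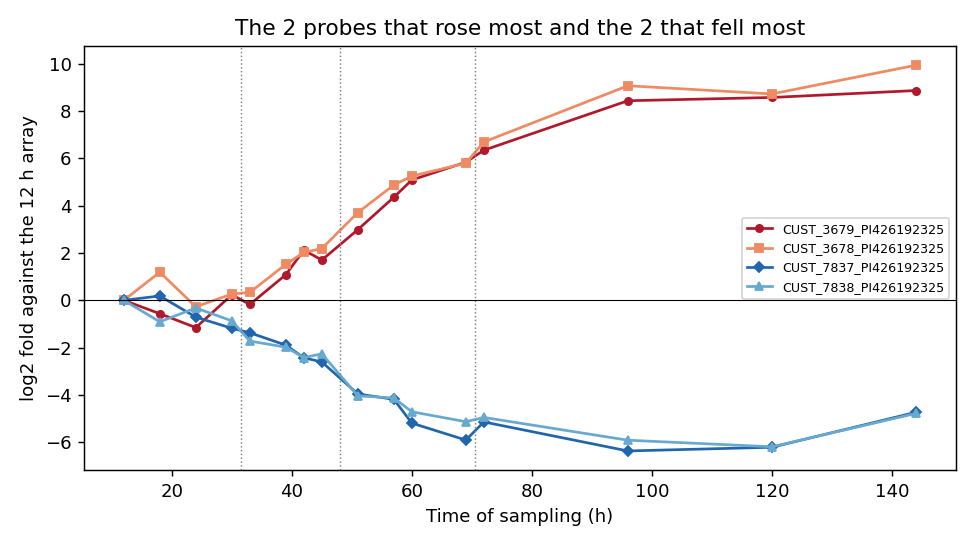
Log2 fold against the 12 h array (vertical axis) at each time of sampling (horizontal axis, h) for the 2 probes that rose most (reds) and the 2 that fell most (blues) between the first and last windows; each point is 1 array and dotted lines part the 4 windows. CUST_3679_PI426192325 and CUST_3678_PI426192325 stood at 0.23 and 0.27 at 30 h and at 8.86 and 9.93 at 144 h; CUST_7837_PI426192325 was lowest at 96 h and CUST_7838_PI426192325 at 120 h.

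The contrasts of adjacent windows ask at which stage of the course probes changed. With all 16 arrays more probes passed the test at the start and the end of the course than in its middle. All contrasts share 1 residual spread per probe, which takes in the change within the outer windows. Arrays lay on average 0.48 to 0.51 from the others of their window in the first and 0.41 to 0.55 in the last. The range was 0.29 to 0.30 in the second and 0.25 to 0.28 in the third. The middle contrast was thus tested against a spread wider than that of its own windows, and its count may understate change there. The contrast of the last with the first window was tested against a spread narrower than that of its windows. Its count may overstate change. The excess of the start over the middle held with any single array left out, but not without 12 h and 18 h together. That of the end did not hold with every single array left out. Without 51 h, 9 probes rose and 9 fell in the middle contrast against 0 in the last (limma, 2498 at an unadjusted p under 0.05 in the last), and the last contrast also had 0 without 57, 96 or 144 h. From 12 to 30 h to 33 to 45 h, 413 probes rose and 612 fell (limma, adjusted p under 0.05). Of these 1025 probes, 545 were also called within the first window, between 12 and 18 h and 24 and 30 h. The median change was 1.76 log2 units among those that rose and -1.22 among those that fell. The counts of rising and falling probes depended on single arrays of both windows. They were 261 and 213 without 12 h, 236 and 152 without 18 h, 264 and 183 without 42 h, 257 and 235 without 45 h, and 772 and 1415 without 30 h, and 248 fell without 39 h. Without both 12 h and 18 h limma called 0 probes, with 1130 at an unadjusted p under 0.05 and a lowest adjusted p of 0.056.

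From 33 to 45 h to 51 to 69 h, 7 probes rose and 6 fell, 0.127% of the probes, with 832 at an unadjusted p under 0.05 (limma). CUST_3678_PI426192325 was among the 7, and CUST_7837_PI426192325 and CUST_7838_PI426192325 were among the 6. With single arrays left out, the number that rose was 0 without 33, 39, 42, 57, 60, 69 or 96 h. There limma gave 317 to 454 rising probes at an unadjusted p under 0.05, and 589 to 856 in both directions together. It was 1 without 24 h or 120 h, 2 without 45 h or 144 h, and 12 without 12 h or 72 h. The number that fell was 0 without 60 h or 69 h (limma, 366 and 272 falling probes at an unadjusted p under 0.05). It was 1 without 39 h, 2 without 57 h, 3 without 96 h and 20 without 12 h.

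From 51 to 69 h to 72 to 144 h, 659 probes rose and 497 fell (limma, adjusted p under 0.05), 11.3% of the probes. The median change was 1.05 log2 units among those that rose and -1.09 among those that fell. These calls depended on single arrays of both windows. Without 96 h or without 144 h, limma called 0 probes, with 1998 (without 96 h) and 2203 (without 144 h) at an unadjusted p under 0.05. Without both, 948 probes had an unadjusted p under 0.05 and the lowest adjusted p was 0.17. The count was also 0 without 51 h or 57 h, with lowest adjusted p-values of 0.058 and 0.056 in limma and 2498 and 2598 probes at an unadjusted p under 0.05. It was 191 up and 170 down without 69 h, and 316 fell without 60 h. Without the 72 h array 1135 rose and 882 fell, and without the 120 h array 1063 rose and 875 fell.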

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

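Within each window of 4 arrays, the gap of the highest or lowest array to the nearest other, divided by the range of the window, was set against Dixon's critical value. The mean distance to the other arrays of the window was chosen as a measure after the distances had been seen. Of 31 windows tested over array-level measures and the 4 named probes, 3 had an array past that value. Chance gives about 1 in 20 for independent values of 1 distribution. Arrays of a window are successive times and mean distances share pairs of arrays, so that share is only a guide.

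The 33 h array had a mean distance of 0.303 to the other arrays of its window, against 0.290 to 0.291 for the others (ratio 0.92). The same array had a median log2 fold of -0.034 against 12 h, the highest of its window (ratio 0.85). In the last window, CUST_3679_PI426192325 stood at 6.34 log2 units above 12 h at 72 h, below the other arrays (ratio 0.83). The 72 h array is the earliest of that window and the probe was named for its rise.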

How the results depend on the processing

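Robust eBayes, the omission of pairs of arrays, the omission of arrays for the named probes between adjacent windows and the centring of distances were chosen after seeing the data. No paired analysis was possible because each time point had 1 array. Quantile normalization (the 12 h array is 0 throughout), the filter on dim probes and eBayes with a trend (no signal levels), and the tests of gene lists and biosynthetic regions (no gene products) were not run. The course count was 2783 by the F-test over windows and 2179 without 12 h and 18 h, and 3839 (without 12 h) to 5474 (without 120 h) with single arrays left out. The late against early counts, up and down, were 784 and 699 for 60 to 144 h against 12 to 33 h, 557 and 455 with the 8 outer arrays alone, 765 and 766 with a 2-fold minimum, 447 and 481 without 96 h and 144 h, and 787 and 688 without 12 h and 18 h. With single arrays left out they ranged from 830 to 1387 and from 771 to 1374, lowest without 144 h. The second against the first window gave 236 to 772 up and 152 to 1415 down with single arrays left out, and 0 and 0 in limma without 12 h and 18 h, where 1130 probes had an unadjusted p under 0.05. The third against the second gave 0 to 12 up and 0 to 20 down, and 10 down after centring on the median. The fourth against the third gave 0 to 1135 up and 0 to 882 down, and 0 and 0 in limma without 96 h and 144 h, where 948 probes had an unadjusted p under 0.05. For all of these the cause was not tested. The counts against 12 h stayed within 1.5 times after centring, and 2 of 16 distances left their interval over resampled probes, which covers no error between arrays, with no distance shifted by over 0.025. No other alternative that was run moved a count by over 1.5 times, and no direction of a named probe reversed. Signal over background is not given in the sources used here, so which probes were dim could not be seen.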

Other observations

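All tests in this part except the counts over splits of the arrays were chosen after the result was seen. Probes with consecutive numbers in the array design often varied together. Among the probes called between the early and late windows, 39 runs of 5 or more consecutive numbers moved the same way, 17 upwards with 149 probes and 22 downwards with 158. The longest rising run held 25 probes, with a median change of 4.42 log2 units. Its median window mean was 2.31 log2 units above 12 h at 12 to 30 h, 6.59 at 33 to 45 h, 6.11 at 51 to 69 h and 6.75 at 72 to 144 h. The longest falling run held 21 probes, with changes of -3.24 to -1.22, and its median went from 0.59 through -0.43 and -1.43 to -1.89. In 1000 shuffles of the calls over the numbers there were at most 4 runs of 5 or more and none longer than 7 (one-sided permutation p = 0.001, the smallest these shuffles can give).

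A hypothesis for these runs is that the probe numbers follow gene order and that neighbouring genes vary together. The mean correlation of the 16-array profiles was 0.18 for probes 1 number apart, against at most 0.016 in 1000 shuffled orders, and it fell to 0.117 at 2 numbers, 0.073 at 5, 0.050 at 10 and 0.015 at 200. The order of rows in the table does not account for it, since neighbours by row correlated at 0.016. Several probes of 1 gene numbered in succession cannot be told apart from neighbouring genes at short range without the probes' genes, although 0.073 at 5 numbers would need blocks of that length. The functions of the runs, including any role in secondary metabolism, are not analysed here.

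The 96 h and 144 h arrays resembled each other (0.23) while the 120 h array lay 0.63 and 0.54 from them. Among probes called with both arrays held out, the 120 h array lay nearer to 72, 96 and 144 h than each array of 12 to 69 h did. The scale ran from 0 at the window of that array to 1 at the late arrays, with a separate set of probes each time. The difference of places was past 2 SD of the 12 single places (0.329) for 10 of these 12 arrays. For 60 h it was only just past (0.330), and for 39 h and 45 h it was under (0.229 and 0.235). A difference of 2 places varies more than a single place, so that bound is too low for it. The differences at 30, 57 and 60 h (0.444, 0.427 and 0.330) therefore do not decide, like those at 39 h and 45 h. The larger ones, from 0.534 (69 h) to 0.890 (12 h), argue against an exchange of labels with those arrays on this measure alone. A second check used 4 probes named with both arrays held out, as given below for 39 h and 45 h. Its bound of 2 SD in each of the 4 probes was not reached for any of the 12 arrays. The differences ran from -1.87 to 1.59 SD at 69 h and from 0.909 to 5.66 SD at 12 h. The 2 measures together thus do not exclude an exchange. The tables argue against error independent from probe to probe as the whole cause, because the difference of the 96 h and 144 h mean from 120 h correlated at 0.16 between neighbouring probe numbers. A candidate source is a component shared with back-and-forth differences earlier in the course, since across probes the step from 69 to 72 h, which shares no array with it, correlated with the step from 120 to 144 h at a Spearman rho of 0.55, the highest of all steps that share no array with it. An exchange among 72 to 144 h cannot be told apart from a course that turns back, since it changed the distance summed along the course by up to -0.404 (with 144 h), and a single wrong label, a flask or array batch, and a true change with time stay open and untested.

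For 39 h and 45 h, where the difference of places was smallest, the values went both ways. An exchange with 120 h lengthened the distance summed along the course by 0.163 and 0.264. The 39 h array lay 0.251 to 0.312 from its window, against 0.438 to 0.455 for 120 h, but it also lay nearer to 96 h and 144 h (0.579 and 0.493) than 120 h did (0.632 and 0.540). With both arrays held out, the rule for named probes gave CUST_3678_PI426192325 and CUST_3679_PI426192325, which stood at 8.72 and 8.57 at 120 h, 1.52 and 1.08 at 39 h and 2.19 and 1.70 at 45 h, against an exchange by 3.46 to 4.11 SD of such a difference. The 2 falling probes it gave did not part the arrays, with differences from -0.346 (39 h) to 1.69 SD (45 h). The bound of 2 SD in each of the 4 probes was thus not reached. These falling probes, CUST_2532_PI426192325 and CUST_6688_PI426192325, stood at -0.918 and -0.991 at 120 h. They stood at -1.355 and -0.859 at 39 h, and at -0.918 and 1.693 at 45 h. Their means over the other late arrays, -5.69 and -4.43, lay below all of these values. CUST_2532_PI426192325 had the same value, -1.355, at 18, 30, 39 and 51 h, and its reliability was not tested.

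At other steps that share no array with it, the Spearman rho with the 120 to 144 h step across probes was 0.40 for 33 to 39 h, -0.42 for 39 to 42 h, 0.43 for 42 to 45 h, -0.30 for 45 to 51 h, -0.36 for 60 to 69 h, 0.45 for 72 to 96 h and -0.46 for 18 to 24 h. The remaining such steps lay between -0.18 (30 to 33 h) and 0.22 (51 to 57 h). Adjoining steps, such as 39 to 42 h and 42 to 45 h, share an array with each other. An error in that array alone would give them opposite signs, so the alternating values are not separate observations. Neighbouring probe numbers correlated at 0.018 to 0.092 in the steps from 30 to 72 h, at 0.27 to 0.32 in the 3 steps before 30 h, and at 0.11 to 0.17 in the 3 steps after 72 h. Probes are not independent replicates, so these correlations describe the arrays and carry no p-value.

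The step from 18 to 24 h was larger than the other steps of 6 h. It was 1.69 times the largest of the other 5. A fault of the 24 h array alone is argued against, because 18 h lay 1.95 times as far from 30 h as 24 h did. With the first window divided, 692 probes were higher and 1116 lower at 24 and 30 h than at 12 and 18 h (limma, adjusted p under 0.05). A change of the culture with time and a batch that separates 12 h and 18 h from the rest both stay open, since the labels give no batch.

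Whether other orders or splits of the arrays call as many probes was tested by counting. Of 100 orders of the 16 arrays, 1, the real one, called as many probes by the spline (4651, highest other 1579). For the windows, 1 of 35 splits of the 8 arrays compared, the real one, called as many in each of the 4 contrasts. These gave 2360 for the last against the first window (highest other 1945), 1025 for the second against the first (highest other 369), 13 for the third against the second (highest other 1) and 1156 for the fourth against the third (highest other 1). Chance can be excluded for these 5 counts only in the sense of a random assignment of the arrays, each at a share under 0.05. Arrays sampled in succession are not exchangeable, so drift or likeness of arrays close in time, which favours the real split, is not excluded. The counts also fell with single arrays left out, to 830 up and 771 down for the last against the first window without 144 h. They fell to 0 in limma for the third against the second without 60 h or 69 h (766 and 589 probes at an unadjusted p under 0.05), and for the fourth against the third without 51, 57, 96 or 144 h (2498, 2598, 1998 and 2203). The split with 1945 calls put 12, 18, 96 and 144 h against 24, 30, 72 and 120 h, so a grouping that does not follow the order of time also called many probes. Whether this comes from a course that turns back or from another source was not tested.

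In 13 probes all 15 deposited arrays lay over 4-fold above 12 h within a 4-fold range, and in 10 probes all 15 lay over 4-fold below 12 h within such a range.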
